A study of Mus musculus with 21 samples.

How the data were processed

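Single cells from 7 mouse samples, pooled with hashtag antibodies in a single 10x Genomics lane, were profiled for RNA and for surface protein with barcoded antibodies. T cell receptor libraries of the same cells belong to the series and were not analysed here. The labels describe 6 thymus samples from bone marrow chimeras, in which marrow of OT-I or OT-II donors was mixed with competitor marrow and moved into a host. OT-I cells carry a transgenic T cell receptor for an ovalbumin peptide on MHC class I, and OT-II cells one for an ovalbumin peptide on MHC class II. Each line has 3 stages, named in the labels as pre-selection, positive selection and negative selection, with 1 mouse per line and stage. The gate was CD44 low, positive for both donor CD45 alleles and for the transgenic Vb5 and Va2 chains, and for pre-selection also CD69 low. Positive and negative selection share that gate and differ in the host, which was wild type for positive selection and RIPmOVA for negative selection. RIPmOVA mice make membrane-bound ovalbumin under an insulin promoter. The chimeras were 14 weeks old and sampled 6 weeks after transplantation. The remaining sample is labelled as spleen of an 8 weeks old wild-type mouse, sorted on CD45 alone. The series' own design text describes a different experiment, an infection with a parasite, and was set aside in favour of the title and the sample labels.

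The deposited RNA values are whole-number counts per gene and cell, and the deposited antibody values are whole-number counts per antibody and cell, both without normalization. Cell Ranger 8.0.1, Seurat (version not given) and the genome build mm10 were used by the authors, per the submitters' processing notes. How cells were filtered and how hashtags were called is not stated. Each of the 10860 cells deposited carries a hashtag number, which assigns it to a sample. No annotation of cell types is among the deposited files. All deposited cells were kept. The files list 55494 genes, of which 24964 have a count, and 180 antibodies, of which 9 are isotype controls and 52 have no count in any cell. Total RNA counts ranged from 1378292 in the sample labelled spleen to 16678346 in OT-I pre-selection. Median RNA counts per cell lay between 4694 and 4784 in the OT-I samples and between 2049 and 2467 in the others.

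Cells were clustered with scanpy 1.11.5 under Python 3.11.15. Counts were scaled to 10000 per cell and log-transformed, genes seen in at least 10 cells were ranked by variability, and 1873 of the top 2000 were used after receptor, immunoglobulin, ribosomal and mitochondrial genes were left out. Leiden clustering at resolution 1 on 15 neighbours and 30 principal components gave 19 clusters. Markers of 19 cell types were fixed before the data were examined, as were the gene lists, the tests, the rule for named genes and most alternatives. The rule that turns markers into names was set after the clusters were seen. It required at least 3 markers and at least a share of 0.5 of the markers at 2 times the median of the other clusters (pseudocount 20 CPM), and at least 1 marker among the 10 leading genes. A cluster whose leading genes held more markers of another type stayed unnamed. By this rule 13 clusters were named and 6 were left with a number. The names come from this rebuilt clustering and can differ from those of the study. Doublet scores came from scanpy's version of scrublet at an expected 6%. Its automatic threshold marked 0 cells and so had not worked. No doublets were removed from the main values, and leaving out the 599 cells in the top 6% of scores was tried as an alternative chosen after this was seen. A cell counted as positive for surface CD4 or CD8 above the point between the components of a Gaussian mixture fitted to centred log ratio values of CD4 or CD8B, with 569 cells within 0.25 of the CD4 threshold and 592 within 0.25 of the CD8 threshold. The threshold cuts a continuous range.

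Counts were summed over the cells of each sample and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr by stage, two-sided) under R 4.3.3. All 6 thymus samples entered each fit, with line as covariate for stages and stage as covariate for lines, which leaves 2 residual degrees of freedom. Adjusted p is by the Benjamini-Hochberg method, and the threshold was 0.05. With 1 mouse per line and stage, a stage test measures a change common to both lines against what the additive model leaves over, including any difference between the lines in their response, and a change within 1 line has no test. The same fit was made on 113 antibodies and within each cell type or cluster with at least 30 cells in each sample compared. For 22 gene lists, camera of limma 3.58.1 was run with a preset correlation of 0.01 and with an estimated correlation, and list members were also adjusted over the list alone. Values within 1 line are log2 ratios of CPM (a gene's counts scaled by the library total) with intervals from the Poisson counts. A list's median within a line was placed among 10000 random lists of the same size matched on expression, as a description of these libraries. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. All such intervals cover counting error only and say nothing of the spread between mice.

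Genes named in the text were chosen by rule. The first part takes, from each gene list, up to 4 members past the threshold with the largest absolute log2 fold change. The second part takes the 8 higher and 8 lower genes past the threshold with a mean of at least 50 CPM that change the same way at all 3 stages (or in both lines), ranked by the smallest ratio, without receptor segments, mitochondrial genes and unnamed gene models. Where no gene passed, list members are given as values, and those shown were picked by size after the values were seen. Gene names are those of the files, and 2 list symbols were matched through synonyms in the reference (Trgc1 and Trgc4).

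The tests were checked on simulated counts with 200 genes changed by known folds. For positive selection against pre-selection over all cells, the test recovered 84.8% of the genes changed 4-fold, 25.4% of those changed 2-fold and 2.99% of those changed 1.5-fold, among 12440 genes. For negative against positive selection these were 74.2%, 22.4% and 4.48% of 12420 genes, and for OT-II against OT-I 81.8%, 43.3% and 7.46%. Genes without a simulated change were called 9, 6 and 10 times in the same order. With an estimated correlation, camera did not call a simulated list changed 2-fold in any comparison (adjusted p = 0.29, 0.175 and 0.192), while the preset correlation did. The preset setting also called 1 unchanged list in positive against pre-selection and 1 in OT-II against OT-I. Genes were simulated independently, so this check cannot show whether the preset correlation is too low. Alternatives covered normalization (RLE), DESeq2 1.42.0, low-count filters, covariates, filters on cells (at least 1000 RNA counts and under 10% mitochondrial), equal cell numbers, restriction to alpha-beta lineage types, samples left out, clustering resolution and surface thresholds. The alpha-beta lineage types are the named types other than gamma-delta-like, without the unnamed clusters and without the cells with the highest doublet scores. After the data were seen, fits with the labels of 2 OT-II libraries exchanged or with both left out were added, as were clusterings without the library labelled spleen and without marker genes, and CD8A in place of CD8B.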

Results

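The libraries allow thymocytes with a transgenic receptor restricted to MHC class I (OT-I) or class II (OT-II) to be compared at the stages that the labels name pre-selection, positive selection and negative selection. The OT-I libraries hold 2858, 2353 and 2415 cells at these stages, and the OT-II libraries 878, 905 and 1076. Median RNA counts per cell were 4754.5, 4694 and 4784 in OT-I and 2100.5, 2327 and 2467 in OT-II, so a gene is seen in fewer OT-II cells at equal expression. The library labelled spleen holds 375 cells with a median of 2049.

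OT-I and OT-II cells that passed the same gate were of different kinds. Many OT-I cells fell in clusters with RNA of the gamma-delta T cell markers Trdc, Trgc1, Trgc4 and Sox13, although they had been sorted on both transgenic alpha-beta chains. These gamma-delta-like cells made up 62.6% (95% interval 60.8 to 64.4) of OT-I pre-selection, 44.0% (42.0 to 46.1) of positive selection and 69.9% (68.0 to 71.7) of negative selection. With filtered cells, clustered and named anew, these shares were 45.8%, 33.4% and 45.4%. The filter kept 2840 of 2858, 2346 of 2353 and 2401 of 2415 OT-I cells, so the cells removed do not account for the lower shares. The shares also stayed under 50% in each OT-I library at resolution 2, without the library labelled spleen and without marker genes. In OT-II, gamma-delta-like cells made up 13.2% (11.04 to 15.6), 11.2% (9.18 to 13.4) and 5.11% (3.87 to 6.60). CD4 and CD8 double-positive (DP) thymocyte-like cells, with RNA of the recombination genes Rag1 and Rag2, were 1.47%, 1.78% and 1.37% of OT-I but 63.6% (60.3 to 66.7), 44.3% (41.0 to 47.6) and 19.7% (17.4 to 22.2) of OT-II. Mature CD8 single-positive (SP)-like cells were 20.6% (19.1 to 22.1), 17.9% (16.4 to 19.5) and 1.04% (0.671 to 1.52) of OT-I and at most 0.569% of an OT-II library. Mature CD4 SP-like cells were 54.2% (51.2 to 57.2) of the OT-II library labelled negative selection and 1.44% (0.767 to 2.44) of the one labelled positive selection. Cluster 3, in which Itm2a leads and 7 of 8 markers of signalled DP thymocytes are raised, held 2.69%, 9.35% and 8.36% of OT-I and 10.0%, 21.1% and 11.8% of OT-II. Clusters left without a name held between 10.9% and 29.0% of a thymus library. The gate selects on receptor chains, CD44 and, for pre-selection, CD69, so these are shares of sorted cells.

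**Figure D1:**
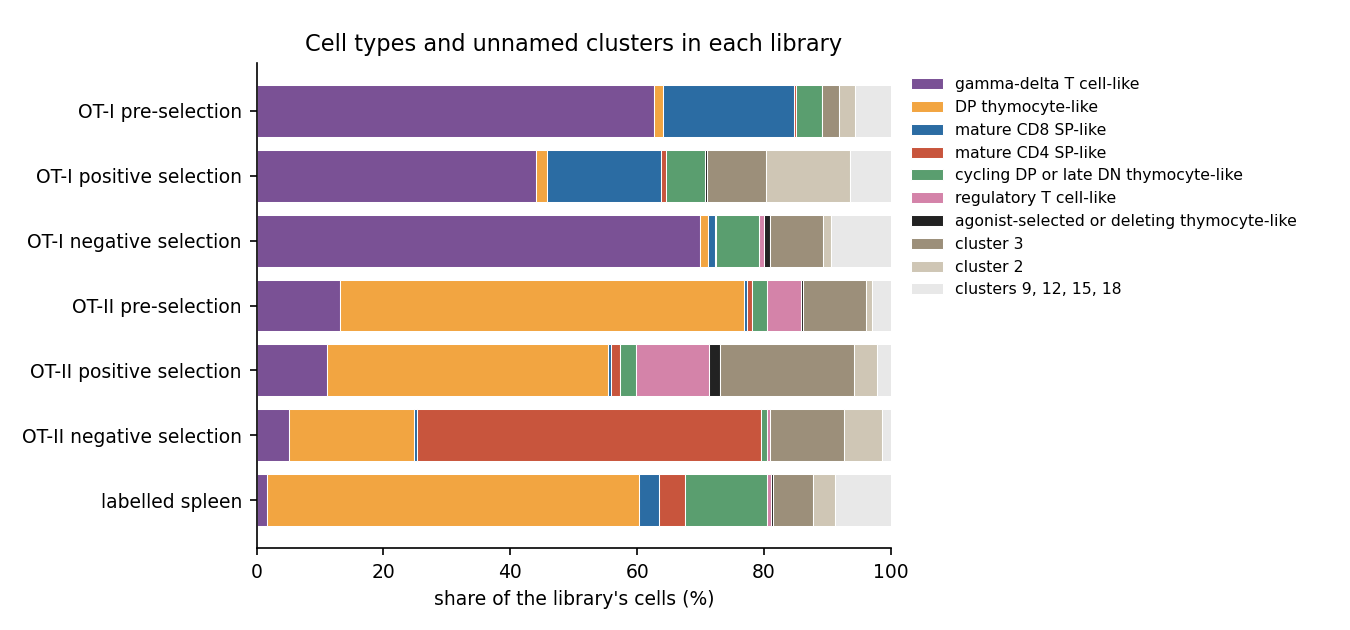
Share of each library's cells (percent, horizontal axis) in each cell type or unnamed cluster, with 1 bar per library and 1 library per line and stage. Gamma-delta-like cells take 44.0% to 69.9% of the OT-I libraries and 5.11% to 13.2% of the OT-II libraries.

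Surface CD4 and CD8 gave the same division. Cells without either made up 67.5%, 50.1% and 80.5% of OT-I and 13.2%, 12.04% and 5.02% of OT-II at the 3 stages. Cells with both made up 5.14%, 11.05% and 7.95% of OT-I and 77.9%, 60.6% and 24.2% of OT-II. CD8 alone was seen on 24.3%, 24.9% and 6.998% of OT-I cells, and CD4 alone on 6.83%, 26.3% and 69.7% of OT-II cells. Of the gamma-delta-like cells 95.8% had neither, of the DP-like cells 91.2% had both, of the mature CD4 SP-like cells 96.0% had CD4 alone and of the mature CD8 SP-like cells 89.1% had CD8 alone.

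**Figure D2:**
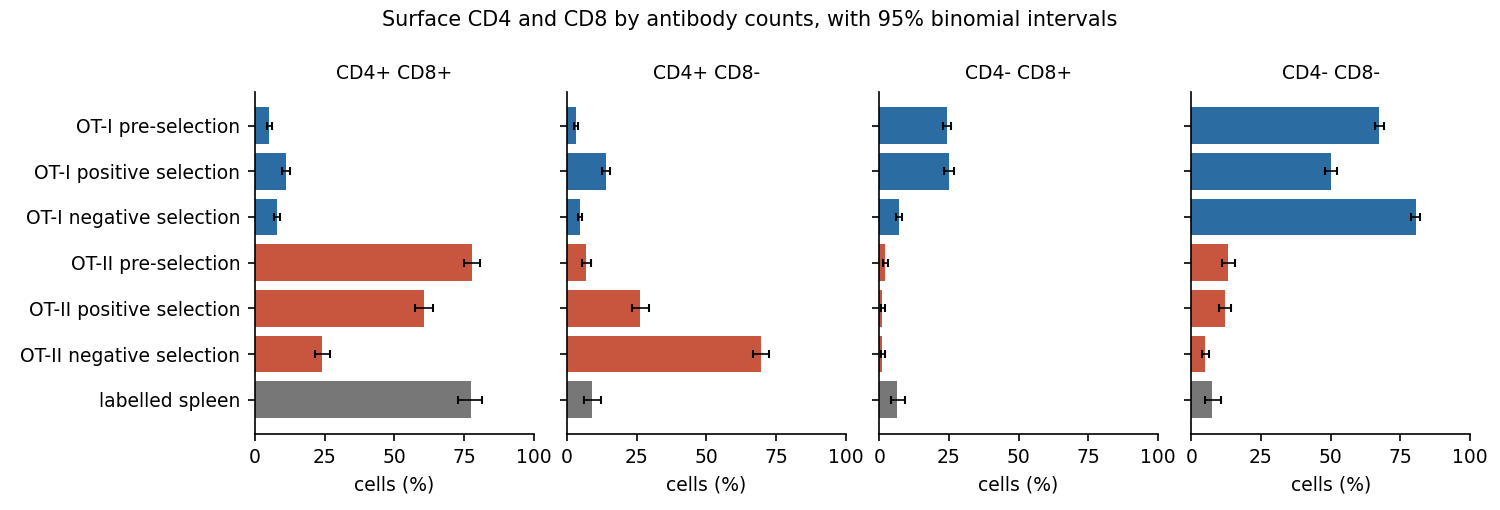
Percent of each library's cells (horizontal axis) by surface CD4 and CD8 from antibody counts, 1 panel per combination and 1 bar per library, with exact 95% binomial intervals. Cells with CD4 alone reach 69.7% in the OT-II library labelled negative selection and 26.3% in the one labelled positive selection.

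Receptor RNA differed between the lines, and the library labelled spleen held cells at odds with its label. Trbv12-1, a gene segment of the Vb5 chain, stood at 3273, 3514 and 3462 CPM in OT-I and at 649, 564 and 348 CPM in OT-II, where Trbv12-2 stood at 1079, 1022 and 865 CPM. These segments are near-identical, so some reads may be assigned to the wrong one. In OT-I, however, Trbv12-2 stood at only 8.33, 7.15 and 8.97 CPM, so most reads there were told apart. The library labelled spleen held 58.7% DP-like cells (53.5 to 63.7), with Rag1 at 598 CPM and Rag2 at 203 CPM, against 133 and 67.5 CPM in OT-II pre-selection. It held no count of the B cell gene Cd79a, where 3 counts would be 2.18 CPM. The OT-II library labelled negative selection held no count of Foxp3, which drives regulatory T cells, where 3 counts would be 0.999 CPM. The other OT-II libraries held 66 counts each, and the OT-I libraries 9, 6 and 8.

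Between pre-selection and positive selection, no single gene passed in edgeR (0 of 12819), and genes of T cell receptor (TCR) signalling stood higher as a list in both lines with a preset correlation only. At an unadjusted p under 0.05 there were 103 genes, and DESeq2 called 2. The TCR signal list (Itm2a, Egr2, Nr4a1 and others) had 14 of 16 members above 0 and a median log2 fold change of 0.37 (camera, adjusted p = 6.0e-07, and adjusted p = 0.543 with an estimated correlation), with 3 members higher when adjusted over the list alone. Its median was 0.30 within OT-I and 0.64 within OT-II. The pre-selection gate was CD69 low and Cd69 is a member of this list, so the sort itself can lower the list there. The OT-I library labelled pre-selection held 20.6% mature CD8 SP-like and 1.47% DP-like cells, against 17.9% and 1.78% in positive selection. Its S1pr1 stood at 94.4 CPM against 64.7 in OT-I positive selection, and its Klf2 at 585 against 435. In OT-I the comparison is thus not one of cells before selection with later ones. Cluster 3 also held more cells in positive selection, with 2.69% and 9.35% of OT-I and 10.0% and 21.1% of OT-II. Counts summed over all cells move with such shares, and the list test cannot tell this from a change within cells. The agonist signal and deletion list rose as well (15 of 18 above 0, median 0.38, adjusted p = 2.0e-04), as did the CD4 lineage list (adjusted p = 0.0147), the CD8aa intraepithelial precursor list (0.0124), the innate-like T cell list (0.0147) and the dissociation stress list (0.0279). The last holds immediate early genes that TCR signals also induce. With an estimated correlation none of these held, with adjusted p = 0.761 for agonist signal and deletion, CD4 lineage and CD8aa precursors, and 0.76 for the other lists. With the labels of the OT-II positive and negative selection libraries exchanged, the agonist list lost its call. Its median was then 0.081 and its test pointed down (camera, preset correlation, adjusted p = 0.994). The remaining lists gave adjusted p of 0.0795 or more, the lowest being the gamma-delta T cell list (median -0.27) and the preselection DP list at 0.0904. For maturation and egress the median was -0.07 although the test pointed up (adjusted p = 0.999), and the B cell list also had a negative median (-0.25) with a test pointing up.

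Members that did not pass over all genes are given as values. Itm2a, an early mark of positive selection, had a log2 fold change of 1.39 ± 0.17 (standard error), with ratios of 1.41 in OT-I and 1.37 in OT-II. Egr2, a TCR-induced transcription factor, had 0.89 (0.97 and 0.78), and Nr4a1, which tracks TCR signal strength, 1.25 (0.88 and 1.46). Zbtb7b, which directs cells to the CD4 fate, had 3.65 (3.31 and 3.49), and Cd40lg, a ligand of helper T cells, 2.62 (2.05 and 4.07). Cd74, the class II invariant chain, was higher only when adjusted over the B cell list alone (2.28 ± 0.38). Among 113 surface proteins edgeR called 0, with 3 at an unadjusted p under 0.05, among them CD69 (0.36, adjusted p = 0.998), which the pre-selection gate itself sets. Without the OT-I negative selection library 31 genes and 8 proteins passed, and without the OT-II one 81 genes and 8 proteins.

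From positive to negative selection, with the labels as given, CD8 coreceptor RNA stood lower in both lines, and 9 other lists went opposite ways in OT-I and OT-II. No gene passed in edgeR (0 of 12819, with 130 at an unadjusted p under 0.05, and 1 by DESeq2). The CD8 lineage list fell (camera, adjusted p = 0.00164, and adjusted p = 0.657 with an estimated correlation), and its members Cd8a and Cd8b1, the 2 chains of CD8, were lower when adjusted over the list alone. Cd8a had a log2 fold change of -1.42 ± 0.27 (-1.76 in OT-I and -1.09 in OT-II) and Cd8b1 -1.50 ± 0.34 (-2.18 and -0.88). The surface proteins CD8A (-1.19) and CD8B (-1.15) did not pass (adjusted p = 0.344 for each). Other lists that fell with the preset correlation, though not with an estimated one (adjusted p = 0.657), were agonist signal and deletion (0.00164), cell cycle (0.0037), regulatory T cell (0.00559), TCR signal (0.00756), preselection DP (0.0229), NK cell (0.0242) and chemokine receptor (0.029). Maturation and egress and MHC class I rose (adjusted p = 0.0272 each, and 0.657 with an estimated correlation). Counts summed over all cells move with the shares of cell types, such as regulatory T cell-like cells at 11.5% and 0.465% of the OT-II libraries labelled positive and negative selection. The interferon response list did not pass (0.0687). Within the lines, agonist signal and deletion had a median of 0.17 in OT-I and -0.99 in OT-II, and maturation and egress -0.22 and 1.19. TCR signal (-0.17 and -0.44) and CD8 lineage (-0.43 and -0.65) moved the same way in both. Gadd45b, a stress and signalling gene, had ratios of 1.23 in OT-I and -5.11 in OT-II, and S1pr1, the receptor that lets mature cells leave the thymus, -0.03 and 2.13. Among proteins 0 of 113 passed in edgeR, with 3 at an unadjusted p under 0.05. Leaving out the OT-I negative selection library gave 991 genes and 15 proteins, and leaving out the OT-II one 250 genes and 17 proteins. With the labels of the OT-II positive and negative selection libraries exchanged, the agonist list rose (median 0.41, adjusted p = 9.4e-06) and the maturation list fell (-0.79, adjusted p = 1.4e-04), each with adjusted p = 0.701 with an estimated correlation. The CD8 lineage list then lost its call (adjusted p = 0.551) with a test pointing up, and Cd8a and Cd8b1 go opposite ways in the lines.

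**Figure D3:**
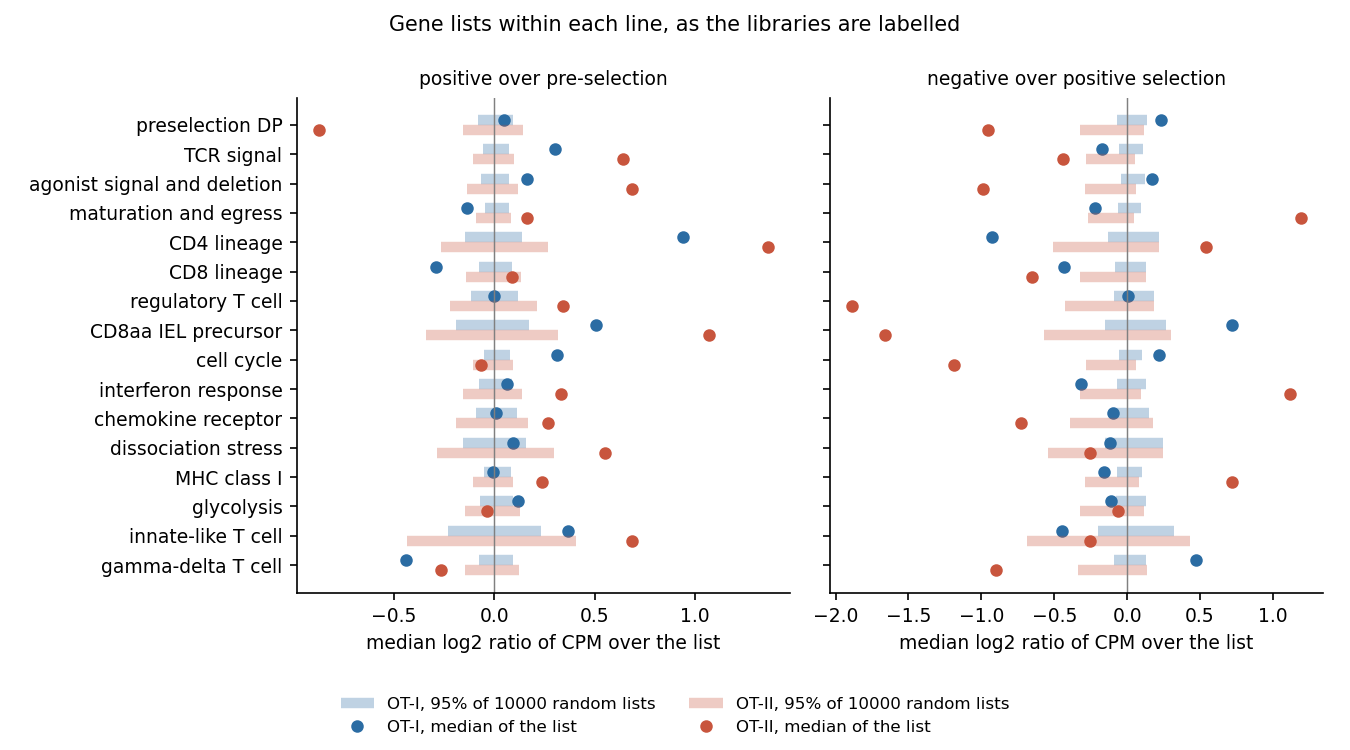
Median log2 ratio of CPM over each gene list (horizontal axis) within OT-I and OT-II, positive over pre-selection on the left and negative over positive selection on the right, with bands for the middle 95% of 10000 random lists matched on expression. The agonist list stands at 0.17 in OT-I and -0.99 in OT-II for negative over positive selection.

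OT-II cells differed from OT-I cells in 1045 of 12819 genes over all cells (495 higher, 550 lower; 3729 at an unadjusted p under 0.05; DESeq2 1083). With 2 stages in the fit the count was 71, and without stage as covariate 2941. Counts summed over all cells move with the shares of cell types, which differ widely between the lines. Gamma-delta-like cells were 44.0% to 69.9% of an OT-I library and 5.11% to 13.2% of an OT-II one. DP-like cells were 1.37% to 1.78% and 19.7% to 63.6%. The fit over all cells cannot tell such shares from a change within cells. Among genes past the threshold, members of the DP thymocyte and CD4 lineage lists were higher, and members of the gamma-delta, cell cycle and CD8 lineage lists, apart from CD8 itself, were lower. The adjusted p of lists given here are with a preset correlation, and no list held with an estimated one (adjusted p = 0.677). In the preselection DP list (adjusted p = 8.5e-04), 5 of 10 members rose, among them Rag1 (3.93) and Rag2 (4.03), which rearrange receptor genes, and Ptcra (3.50), the pre-TCR alpha chain. In the TCR signal list (8.5e-04), 5 of 16 rose, including Itm2a (1.42), Egr2 (1.32), Egr1 (0.79) and Cd5 (0.93), a brake on TCR signalling. Within alpha-beta lineage types alone, Egr2 (-0.22) and Egr1 (-0.17) turned direction without passing. That set leaves out the unnamed clusters, among them cluster 3, in which Egr1 and Egr2 are raised. The turn therefore does not describe those cells. In the CD4 lineage list (0.028), 3 of 6 rose, including Cd4 (3.53 ± 0.40, adjusted p = 0.0162) and Zbtb7b (5.64 ± 0.92, adjusted p = 0.030). All 6 gamma-delta T cell genes fell (4.2e-04), among them Trdc (-1.81) and Trgc1 (-2.37), constant regions of that receptor, and Blk (-2.01), a kinase of these cells. In the CD8 lineage list (0.028) 4 of 8 fell, including Itgae (-3.14 ± 0.15, adjusted p = 0.0052), the CD103 integrin chain, Runx3 (-1.51), which sets the CD8 fate, and Nkg7 (-2.36). Its member Cd8a rose (1.32 ± 0.22, adjusted p = 0.0303), while surface CD8A (0.58, adjusted p = 0.134) and CD8B (0.83, adjusted p = 0.0710) did not pass. Cell cycle genes fell (3.8e-04, 4 of 12, among them Mcm5 at -1.10 and Pcna at -0.90), as did the glycolysis list (0.0157) with Pgk1 (-0.54) past the threshold. Adjusted over the list alone, 6 preselection DP genes and 4 CD4 lineage genes were higher, 6 CD8 lineage, 11 cell cycle and 4 glycolysis genes were lower, and 2 CD8 lineage genes were higher. For the myeloid list the median was 0.03 although the test pointed down. The regulatory T cell list did not pass as a whole (0.0603), with 3 members higher (6 when adjusted over the list alone), among them Ctla4 (2.50), an inhibitory receptor. In maturation and egress (0.46) Gimap6 (0.55) was higher and Bcl2 (-0.66), a survival gene, was among those lower.

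By the rule for consistent changes, the genes higher at all 3 stages included Rnf43 (7.34 ± 0.15, adjusted p = 1.5e-04), a brake on Wnt receptors, at 652, 582 and 433 CPM in OT-II against 2.82, 3.58 and 2.88 CPM in OT-I. Trac (3.96 ± 0.13, adjusted p = 0.00136), the alpha chain constant region, Ldhb (2.68), Ntrk3 (2.35), Nsg2 (2.10) and Ets2 (1.86) were higher too. Those lower at all 3 stages included Cpa3 (-3.05), Cd163l1 (-2.81), Alox5ap (-2.80), Gem (-2.71) and Igfbp4 (-2.51), which lead the gamma-delta-like clusters. Of the 113 proteins, 9 changed (4 higher, 5 lower; 30 at an unadjusted p under 0.05). Among those lower were the integrin beta 7 chain (-2.26, adjusted p = 0.0102), CD103 (-1.93), CD48 (-1.003) and Ly6C (-0.71), and higher were CD155 (1.49), CD150 (1.04), integrin alpha 6 (1.007) and CD95 (0.70). CD4 (2.22) did not pass (adjusted p = 0.0632). The gene count was 80 without OT-I pre-selection, 171 without OT-I positive selection, 3320 without OT-I negative selection, 87 without OT-II pre-selection, 268 without the OT-II library labelled positive selection and 3464 without the one labelled negative selection. Of the 44 genes chosen by rule, 26 lost the threshold in at least 1 such fit (highest adjusted p = 0.262). The protein count was 0 without any single pre- or positive selection library and 45 or 49 without OT-I or OT-II negative selection. Within alpha-beta lineage types alone, 4 genes passed (Cd4 at 3.87, Rnf43 at 7.21, Trbv12-2 at 7.79 and Trbv31 at 6.71). That fit has fewer cells, leaves out the unnamed clusters and still joins different types. Of the 44 genes chosen by rule, 38 kept their direction there without passing, and 4 turned, among them Alox5ap (0.09) and Trgc4 (0.24).

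**Figure D4:**
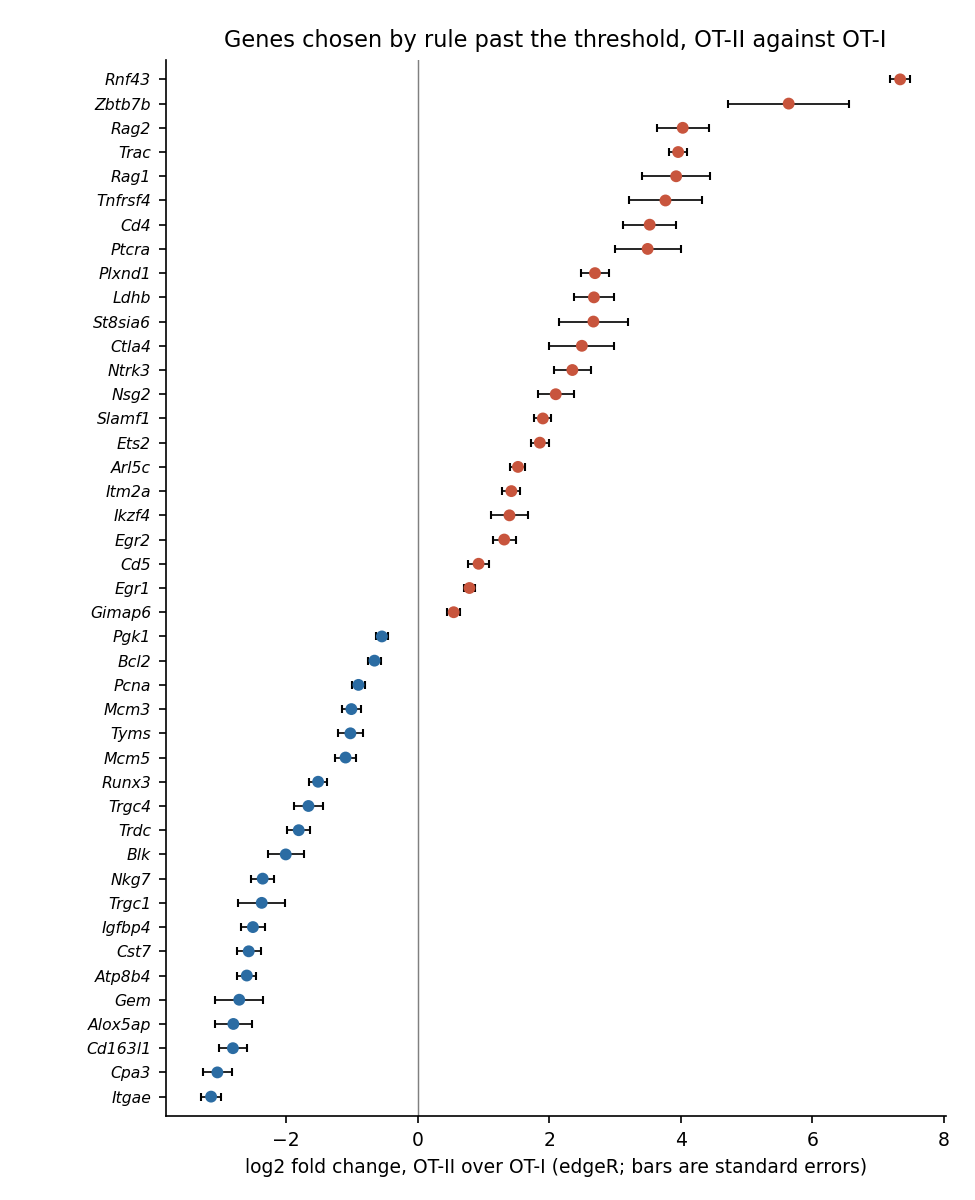
Log2 fold change of most genes chosen by rule that passed the threshold, OT-II over OT-I (horizontal axis), with points for the edgeR estimate over 3 libraries per line and bars for standard errors. Rnf43 stands at 7.34 and Itgae at -3.14.

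Within gamma-delta-like cells, CD8 genes were lower in negative than in positive selection, from a low level. Cd8b1 stood at 7.22 CPM in cluster 13 and 68.2 CPM in cluster 8 of this type, against 1416 CPM in the mature CD8 SP-like cluster. Mature CD8 SP-like cells were 17.9% of OT-I positive selection and 1.04% of OT-I negative selection. The fit cannot tell a change in gamma-delta-like cells from a few CD8 cells placed among them. Of 10950 genes tested, 6 rose and 7 fell. Cd8b1 (-2.25 ± 0.20, adjusted p = 1.3e-12), Cd8a (-1.61 ± 0.27, adjusted p = 4.3e-04), and the chemokine Ccl4 (-1.93) fell, while Slamf6 (0.91) and Top2a (0.71) rose. Ly6a (0.71), Ube2c (0.85) and Maf (-0.50) also changed but are leading genes of clusters 8, 10 and 17 in this type. Top2a too stands at 198 CPM in cluster 10, against 23.6 CPM or less in clusters 8, 13, 14 and 17. The mix of these clusters is not held in this fit. Without line as covariate 0 genes passed in edgeR (42 at an unadjusted p under 0.05), with exchanged labels 5 and without both of these OT-II libraries 3. The count was 2 without OT-I positive selection, 6 without the OT-II library labelled positive selection, 20 without the OT-I and 20 without the OT-II pre-selection library, and 32 and 25 without OT-I or OT-II negative selection. Between pre-selection and positive selection edgeR called 0 (111 at an unadjusted p under 0.05), with 9 without OT-I pre-selection, 2 without OT-I positive selection and 1 without OT-II negative selection. OT-II differed from OT-I in 430 genes (223 higher, 207 lower), 224 of them also called over all cells and 222 in the same direction. Ifit1, Ifit3, Isg15, Usp18 and Ifi27l2a of the interferon response list (5 of 10) were higher, and Bcl2, Itgb7 and Klf2 of maturation and egress were among those lower. Cluster 17, with Klf2 at 225 CPM against 1243 in cluster 8, holds 41 of 116 OT-II and 265 of 1790 OT-I cells of this type in pre-selection, and the mix of clusters is not held here either. The count was 196 without OT-I positive selection and 208 without the OT-II library labelled positive selection.

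Within DP-like cells, OT-II differed from OT-I in 1216 of 5955 genes (443 higher, 773 lower), although the OT-I libraries hold 42, 42 and 33 such cells. In maturation and egress 8 genes were lower, among them S1pr1 and Klf2, which go with exit from the thymus, and Il7r, and in glycolysis Aldoa, Gapdh, Ldha and Pkm were higher. The lines are spread differently over the clusters of this type, with 23, 17 and 10 OT-I cells in cluster 6 and 18, 25 and 21 in cluster 7, against 505, 351 and 177 OT-II cells in cluster 6 and 39, 36 and 34 in cluster 7. S1pr1 stands at 99.0 CPM in cluster 7 and 3.79 in cluster 6, Klf2 at 114 and 26.9, and Il7r at 252 and 7.57, and the mix of clusters is not held in this fit. Cluster 7 also has fewer RNA counts per cell, with a median of 1378 against 1970 in cluster 6. Of the 1216, 159 were also called over all cells, 99 of them in the same direction. The count was 786 without OT-I pre-selection, 402 without OT-I positive selection and 488 without the OT-II library labelled positive selection. Neither stage comparison called a gene in edgeR (89 and 147 at an unadjusted p under 0.05). Between pre-selection and positive selection, leaving out any single library gave 1 to 4 genes. Between positive and negative selection it gave 1 without OT-I positive selection, 10 without OT-I negative selection, 2 without OT-II pre-selection and 12 without OT-II negative selection.

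Within cluster 3, Bcl2 (1.13), a survival gene, rose from pre-selection to positive selection, and Cd8a (-1.02), Cd8b1 (-0.95), Ly6d (-2.04), Smc4 (-0.87) and Bambi-ps1 (-2.26) fell. Itm2a (0.92, adjusted p = 0.0101) passed too but leads this cluster. These 7 of 6530 genes became 27 without OT-I pre-selection, 3 without OT-I positive selection, 51 without OT-I negative selection, and 25, 14 and 49 without the OT-II libraries in the same order. Without line as covariate, and without both of the OT-II libraries labelled positive and negative selection, 0 passed. Negative against positive selection gave 0 (225 at an unadjusted p under 0.05), and 2, 5 and 17 without an OT-I library and 2, 1 and 8 without an OT-II one. OT-II differed from OT-I in 668 genes (238 higher, 430 lower), with Cd69, Cd5, Cd6, Egr2 and Nr4a1 of TCR signal and Cd4, a leading gene of this cluster, and Zbtb7b higher. In glycolysis Aldoa, Gapdh, Pgk1 and Pkm were lower in OT-II here. Within DP-like cells, where the mix of clusters was not held, Aldoa, Gapdh and Pkm were higher. The count within cluster 3 was 343 without OT-I positive selection and 331 without the OT-II library labelled positive selection. In cluster 2, 4 of 4104 genes differed between negative and positive selection with 1 residual degree of freedom. Nr4a1 (-3.00), Trdv1 (-3.15) and Cd74 (-2.63), a leading gene of this cluster, fell and Lef1os1 (1.98) rose, and without OT-I pre-selection 2 passed. Without line as covariate 0 passed in edgeR (66 at an unadjusted p under 0.05), and with exchanged labels 16.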

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

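The tests of depth between the OT-II libraries, of CD45.1 on DP-like cells, of gamma-delta-like cells in the library labelled spleen, of a thymus sample under the spleen label and of the gamma-delta antibody, with the threshold of 60 counts, were chosen only after the results they address were seen, as was the fit with exchanged labels. The differences between the lines given here were not tested, since each line and stage has 1 mouse.

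From positive to negative selection, OT-I and OT-II moved in opposite directions in many measures. In OT-II, mature CD4 SP-like cells rose by 52.7 percentage points and surface CD4 single-positive cells by 43.4, while in OT-I they changed by -0.641 and -9.43. Agonist-selected or deleting thymocyte-like cells changed by -1.77 points in OT-II and 0.739 in OT-I, regulatory T cell-like cells by -11.03 and 0.743, gamma-delta-like cells by -6.05 and 25.8, and cells without surface CD4 and CD8 by -7.03 and 30.4. Median log2 ratios in OT-II and OT-I were -0.96 and 0.23 for the preselection DP list, -0.99 and 0.17 for agonist signal and deletion, 1.19 and -0.22 for maturation and egress, 0.54 and -0.93 for CD4 lineage, and -1.66 and 0.72 for CD8aa intraepithelial precursors. They were -1.19 and 0.22 for cell cycle, 1.12 and -0.32 for interferon response, 0.72 and -0.16 for MHC class I, and -0.90 and 0.47 for gamma-delta T cells. From pre-selection to positive selection, maturation and egress had 0.16 in OT-II and -0.13 in OT-I.

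An exchange of the labels of the OT-II positive and negative selection libraries may account for this pattern. If so, the agonist list should be lower within cluster 3 of the OT-II library labelled negative selection. Its median there was -0.257 (95% bootstrap interval -0.508 to 0.031) against 0.142 (-0.252 to 0.373) in OT-I. Both intervals include 0, so the exchange and a difference between the lines in their response to the RIPmOVA host cannot be told apart. A difference in depth is argued against by a log2 ratio of median counts of 0.084 in OT-II, with the same sign in OT-I (0.027). Without the highest doublet scores, mature CD4 SP-like cells still made up 56.4% of that library. This cannot decide on doublets, since 1023 of its 1076 cells were kept and the share had little room to fall.

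The library labelled spleen stood out because it is outside the comparisons and holds 58.7% DP-like cells, with Rag1 at 598 CPM and Rag2 at 203 CPM. Sorted OT-II thymocytes carrying its hashtag are argued against by CD45.1, whose mean antibody count on its DP-like cells was 0.172 times that on OT-II DP-like cells (4.33, interval 3.93 to 4.77, against 25.2, 10.5 to 54.1). OT-II pre-selection (41.1) raises that mean, but the other OT-II libraries also stood above it, at 10.6 and 11.05. Against OT-I DP-like cells the ratio was 0.408 in pre-selection, 0.446 in positive selection and 0.644 in negative selection, whose interval (5.79 to 7.70) also lies above. Sorted OT-I cells are argued against by the gamma-delta-like share, 1.6% here and at least 44.0% in each OT-I library. OT-I chimera thymocytes from outside the sort gate stay open, since the ratio of 0.644 exceeds the limit of 0.5. OT-II chimera thymocytes from outside the gate stay open too, since the OT-II cells compared were sorted for both donor CD45 alleles. Of its DP-like cells, 2.27% (5 of 220) are among the highest doublet scores. That gives no sign of doublets, but the automatic threshold of these scores had not worked, so it is weak evidence. A thymus sample under a spleen label may be the source, and the Rag1 value of 598 CPM has the size this needs, but that test uses the values that raised the question. By surface antibodies, 77.3% of its cells (72.8 to 81.5) carried both CD4 and CD8, and Cd79a, Igkc and Ms4a1 had 0 counts. These values are at odds with a library of spleen cells. They do not tell a mislabelled thymus sample from thymocytes of another source that carry its hashtag. No biological explanation was tested.

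Between 44.0% and 69.9% of the cells of an OT-I library lay in clusters with gamma-delta marker RNA despite the alpha-beta gate. Gamma-delta T cells that passed the gate are argued against by the gamma-delta TCR antibody, whose mean on these cells was at most 1.03 times that on mature CD8 SP-like cells in any OT-I library. The antibody can stain, since 9 cells exceed 60 counts (up to 245) with a median of 106, against means of 12.3, 12.7 and 11.7 on the gamma-delta-like cells of the OT-I libraries. TCRB stood at 0.51, 0.49 and 0.51 times that on mature CD8 SP-like cells, so these cells bound less of that antibody. The higher depth of OT-I is argued against, since with each cell thinned to 1000 counts the lowest OT-I share of cells with a marker count was 3.21 times the highest OT-II share (51.7% against 16.1%). Cells without CD4 and CD8 that carry the transgenic alpha-beta receptor and a gamma-delta-like RNA profile may explain it. That is a hypothesis found in these data, and a difference between the lines stays open with it.

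For OT-II against OT-I, the 6 samples can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. In each case 1 split, the real one, gave as large a count. Over all cells it gave 1045 genes and the highest other split 0, for proteins 9 and 1, within gamma-delta-like cells 430 and 1, within DP-like cells 1216 and 0, and within cluster 3 668 and 0.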

How the results depend on the processing

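The exchange of OT-II labels, leaving out both of these libraries, clustering without the spleen-labelled library or without marker genes, removal of the highest doublet scores and the use of CD8A were chosen after seeing the data. Over all alternatives, 98 counts of changed genes or proteins stayed within 1.5 times the value reported and 90 did not. Of the percents, 83 stayed within their 95% intervals and 70 moved. Of the other values, 437 kept direction and side of the threshold, 125 kept direction and lost the threshold, 15 reversed and 3 moved. All 76 list medians within a line stayed in range when counts were scaled without ribosomal and mitochondrial genes. Unless stated, the cause was not tested.

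Positive against pre-selection called 2 genes without a low-count filter, 2 with DESeq2, 28 with 2 stages in the fit and 0 to 81 with 1 library left out; proteins 0 to 8. Negative against positive selection called 1 with DESeq2 and 0 to 991 with 1 library left out; proteins 0 to 17. OT-II against OT-I called 1713 genes without a filter, 2941 without covariate, 4 in alpha-beta lineage types (fewer cells), 71 with 2 stages, 2138 with exchanged labels, 1612 without both OT-II libraries and 80 to 3464 with 1 left out. Its proteins were 18 without covariate and 0 to 49 with 1 left out. With an estimated correlation 0 lists were called in any comparison, and the simulated 2-fold list was missed at that setting too. The preset setting called that list, and 1 unchanged list as well in positive against pre-selection and in OT-II against OT-I.

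Within gamma-delta-like cells, positive against pre-selection called 8 without both OT-II libraries and 0 to 9 with 1 left out. Negative against positive called 0 without covariate, 5 exchanged, 3 without both and 2 to 32. OT-II against OT-I called 177 without both and 196 to 384. Within DP-like cells, positive against pre-selection called 2 without a filter, 8 exchanged, 11 without both and 1 to 4. Negative against positive called 2 without a filter, 3 exchanged and 0 to 12. OT-II against OT-I called 444 without both and 402 to 1067. Within cluster 3, positive against pre-selection called 30 without a filter, 0 without covariate, 61 exchanged, 0 without both and 3 to 51. Negative against positive called 3 without a filter, 6 exchanged and 1 to 17. OT-II against OT-I called 277 without both and 331 to 662. Within cluster 2, negative against positive called 0 without covariate, 16 exchanged and 2 with 1 left out. A library left out leaves its line and stage empty, and the other library of that stage is assumed to vary like the others.

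With exchanged labels, list medians or test directions reversed for agonist signal and deletion in positive against pre-selection (0.081), and in negative against positive selection for preselection DP (0.40), TCR signal (0.014), agonist signal and deletion (0.41), maturation and egress (-0.79), CD8 lineage (-0.25), regulatory T cell (0.64), cell cycle (0.50), chemokine receptor (0.27), MHC class I (-0.56) and NK cell (-0.23). For CD8 lineage, NK cell and the agonist list in positive against pre-selection, median and test differ in sign there, and the test alone turned. In alpha-beta lineage types alone, which leave out the unnamed clusters, Alox5ap (0.087), Egr1 (-0.17), Egr2 (-0.22) and Trgc4 (0.24) reversed between lines. Of the 44 genes chosen by rule for the lines, all kept direction and threshold with RLE, filtered cells, equal cell numbers, no covariate, no filter, no doublets or exchanged labels, and 43 with DESeq2. With 1 library left out, 18 did so in every such fit, with 2 stages 17 and without both OT-II libraries 37.

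Gamma-delta-like shares at the 3 OT-I stages were 58.1%, 40.3% and 63.2% at resolution 0.5, 48.4%, 34.7% and 48.4% at resolution 2, 45.8%, 33.4% and 45.4% with filtered cells, 44.8%, 32.3% and 45.5% without the spleen-labelled library, and 49.0%, 34.9% and 48.9% without marker genes. In each of these settings the cells were clustered and named anew. In OT-II they were 10.4%, 8.07% and 3.53% at resolution 2, 10.8%, 7.74% and 3.31% with filtered cells, 7.86%, 5.75% and 3.07% without the spleen-labelled library, 10.4% and 7.85% without marker genes in the first 2 stages, and 8.81% and 3.23% in the last 2 without doublets. Mature CD8 SP-like shares of OT-I were 18.6%, 16.1% and 0.497% at resolution 2, and in negative selection 0.666% with filtered cells and 2.20% without marker genes. Mature CD4 SP-like shares at resolution 2 were 0.331% and 50.5% in the OT-II libraries labelled positive and negative selection. DP-like shares of OT-II were 34.3%, 20% and 10.8% at resolution 2, 60%, 35.5% and 12.9% with filtered cells, and 69.9% and 50.3% in the first 2 stages without marker genes. In the spleen-labelled library they were 52.0% at resolution 0.5 and 52.5% with filtered cells. No cluster was named mature CD4 SP-like at resolution 0.5, nor regulatory T cell-like with filtered cells, at resolution 2 or without the spleen-labelled library.

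Cells without surface CD4 and CD8 were 71.1%, 59.6% and 87.8% of OT-I with raised thresholds, 63.9%, 43.4% and 75.3% with lowered ones and 65.6%, 47.3% and 77.7% with CD8A. CD8 alone was 26.1%, 27.6% and 9.77% of OT-I with CD8A, and 20.95% and 5.63% of positive and negative selection with lowered thresholds. CD4 with CD8 was 64.8%, 44.6% and 18.4% of OT-II with raised thresholds, and in positive and negative selection 69.0% and 28.5% with lowered ones and 65.4% and 26.9% with CD8A. CD4 alone was 30.2%, 19.8% and 21.4% of OT-II positive selection with raised and lowered thresholds and with CD8A, and 66.5% of negative selection with lowered ones. No paired analysis was possible because each library comes from its own mouse. Over all cells, most simulated changes of 2-fold or less were missed.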

Other observations

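The test of the genes beside Rnf43, with its threshold, was chosen only after the result was seen. Cluster 12, with Ccl5, Gzmk, Cxcr6, Il2rb and Klrd1 among its leading genes, held 41 of 2415 cells of OT-I negative selection (1.70%, 95% interval 1.22 to 2.30) and 0 of 2858 and 0 of 2353 cells of the other OT-I libraries. The OT-II libraries held 1, 4 and 1 such cells and the library labelled spleen 5 of 375 (1.33%, 0.434 to 3.08), a share close to that of OT-I negative selection. Agonist-selected or deleting thymocyte-like cells, led by Nr4a1, Gadd45b and Nr4a3, were 24 of the OT-I negative selection cells (0.994%, 0.638 to 1.48) and 6 of the positive selection cells. In OT-II they were 16 cells of the library labelled positive selection (1.77%, 1.014 to 2.86) and 0 of 1076 of the one labelled negative selection.

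Regulatory T cell-like cells were 5.35%, 11.5% (9.49 to 13.8) and 0.465% of OT-II and 0%, 0.0850% and 0.828% (20 cells) of OT-I. Dntt, which adds bases at receptor junctions, stood at 341, 289 and 357 CPM in OT-I and 685, 382 and 230 CPM in OT-II at the 3 stages. The DP-like cells of the library labelled spleen lay mostly in cluster 4 (154 cells, with 38 and 28 in clusters 6 and 7), while those of OT-II lay mostly in cluster 6 (505, 351 and 177 cells).

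Rnf43 RNA in OT-II may reflect a difference at its place in the genome that reaches the genes beside it, on chromosome 11 from 87663087 to 87735539. The 6 nearest tested neighbours had a median log2 fold change of 1.81 between the lines, and 4 of them passed as higher, among them Septin4 (2.63) and Tspoap1 (1.65). Of the other tested genes 0.80% (95 of 11876) had neighbours with as high a median. Among the 456 other genes called higher it was 76, so a raised neighbourhood is less rare beside called genes, which include receptor segments that lie together. The threshold for this test was set with the neighbours' values already known, so the test cannot serve as independent evidence. Where the OT-II transgene lies is not in these data, and a transgene or a strain difference at this place stays untested.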
